A study of Homo sapiens with 12 samples.

How the data were processed

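HEK293 cells, an established line derived from human embryonic kidney, were grown in low oxygen and received 1 µM epoxomicin, an inhibitor of the proteasome, per the labels' protocols. RNA was taken without treatment at 0 h and after 1 h and 6 h of treatment, with 4 arrays in each of the 3 groups and 12 arrays in all. Biotin-labelled cRNA was hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays, which carry 54675 probe sets, per the labels. The untreated arrays stand for 0 h alone, so time in culture and handling varied together with treatment. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical in part.

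The submitters' processing notes name GCOS, the array maker's software, with no version. The deposited values were used as log10 values: they run from 4.67e-16 to 4.45, with a median of 0.383 on each array. The transform, its base and the step between arrays are not given in the sources used here. Hybridisation controls set the scale: over bioB, bioC, bioD and cre, added at 1.5, 5, 25 and 100 pM, the deposited value rose by 1.18 ± 0.0142 (SD, n = 12) per 10-fold concentration. These are different probe sets, and the steps between them were uneven: 0.84 from bioB to bioC, 1.05 from bioC to bioD and 1.67 from bioD to cre, where a natural log would give 2.30. The lower steps lie nearest to a base of 10 and the highest one lies between the bases, so fold changes hold only as far as that reading does. The deposited values never fall below 0, and no detection limit is given in the sources used here, so fold changes of dim genes are uncertain in size. After sorting, the 12 columns held the same values (largest difference 0), so the table had been quantile-normalized with the 62 control probe sets included, and no change in total RNA per cell can be seen. Direction needs no setting, because each array carried 1 sample. Detection calls were not used here, and the precision is limited by the number of arrays.

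Values were divided by log10(2) to give log2 levels. A probe set was kept when it exceeded the median of its array, controls left out, on at least 4 of the 12 arrays, which left 29062. Names came from the platform annotation of 2016. Of all probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 were not listed; 41043 of the first kind matched the RefSeq gene table of assembly GRCh38.p14 by Entrez ID, and 0 symbols changed. A gene was represented by its kept probe set of 1 symbol with the highest mean over the 12 arrays. This gave 12928 genes, of which 6636 had other kept probe sets. Kept probe sets with several symbols (1143) or not listed (3257) were tested under their own IDs and name no gene.

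Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 12 arrays, group means with no covariate), with Benjamini-Hochberg adjustment over all genes of a comparison. A gene is said to rise or fall where the adjusted p was below 0.05, and changes of at least 2-fold were counted separately. Errors of fold changes are standard errors of the fit, with n = 4 arrays per group. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 of 28 lists with at least 5 tested members, and again with the correlation estimated from the residuals. On simulated data of the same 12928 genes for 6 h against 0 h, 68.8% of genes seeded with a log2 change of 0.5, 97.5% of those with 1 and 100% of those with 2 were recovered. The false share of calls was 3.89%. For 1 h against 0 h the shares were 73.8%, 97.5% and 100%, with 3.80% false calls. In both simulations 200 genes were seeded and the noise was independent between genes. In the real data 6630 genes were called at 6 h, so the simulated shares do not describe that comparison. Errors from normalizing arrays on which many genes move were not simulated.

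The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each comparison with 0 h, the 6 rising and 6 falling genes with the largest change among called genes whose groups did not overlap on any array, and 3 of each for 6 h against 1 h. It added up to 3 called members with the largest change in each list (or, with none called, the member with the largest moderated t) and a fixed panel of stress genes. Uncharacterised and sex-linked symbols were passed over. HSPA1A and HSPA1B belong to the panel and were not tested as genes, because no kept probe set carries either symbol alone. Genes named outside the rule are marked as chosen after their values were seen. Metallothionein and histone genes have near-identical relatives, so their probe sets cannot be assigned to single genes with certainty.

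RNA quality was followed by the log2 ratio of 3' to 5' signal of the GAPDH and ACTB control probe sets, with exact two-sided permutation tests; 4 against 4 arrays allow no p below 0.0286. Alternatives covered the scaling between arrays, the filter, the choice of probe set, the arrays in the fit, the replicate number as a block, the prior, array weights, the threshold, the list test and the removal of each array in turn. No coordinates are given, since the genome build behind the table was not used here.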

Results

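Transcript levels were measured on 12 arrays of HEK293 cells: 4 untreated at 0 h, 4 after 1 h and 4 after 6 h of 1 µM epoxomicin. Epoxomicin is a peptide epoxyketone that binds covalently to the catalytic subunits of the proteasome, the protease that degrades ubiquitin-tagged proteins. The series asks how the expression profile changes when the proteasome is inhibited. Within groups, arrays correlated at r = 0.989 to 0.993 across genes, and principal component 1, with 65.8% of the variance, set the 6 h arrays apart. The 0 h arrays serve as the background for both treated groups.

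After 1 h, immediate early genes, which respond to a stimulus without prior protein synthesis, were higher, and few other genes passed the test. EGR1 (probe set 227404_s_at), a zinc finger transcription factor, rose by log2 3.64 ± 0.08 (12.5-fold; limma adjusted p = 7.30e-12). FOS, a component of the AP-1 transcription factor, rose by 1.75 ± 0.11, IER2 by 1.42 ± 0.08 and the EGR1 relative EGR3 by 1.14 ± 0.17. These were the 4 genes that changed at least 2-fold, and EGR3 stood at 0.93 without 1 h replicate 2. At 0 h the log2 level of FOS was 1.21 on replicate 3 and that of EGR3 1.39 on replicate 2. The medians of the other 0 h arrays were 1.59 and 1.72. These levels lie near the array median of 1.27, so the sizes of both rises are uncertain. ATF3, a stress-induced transcription factor, rose by 0.95 ± 0.08, the phosphatase gene DUSP1 by 0.85 ± 0.07, MYC by 0.82 ± 0.10 and JUN by 0.51 ± 0.08. NFKBIA, whose product holds NF-kappaB inactive, changed by -0.86 ± 0.10, and the chemokine gene CXCL8 by -0.78 ± 0.09. CYP1B1, a cytochrome P450, changed by -0.60 ± 0.08 and PGBD5 by -0.59 ± 0.07.

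In all, 57 of 12928 genes passed at 1 h (26 rose, 31 fell), and 1650 had an unadjusted p below 0.05. For 8.73% of genes the groups did not overlap on any array, where chance alone gives 2.86%. The test may therefore have missed smaller changes. The count fell to 29, 28, 34 and 34 without untreated replicates 1 to 4, and to 34, 28 and 30 without 1 h replicates 1 to 3. Other ways of testing gave from 22 genes at an adjusted p of 0.01 to 142 with an intensity trend and robust prior.

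Among the lists at 1 h, 3 were shifted up. Of 36 immediate early genes, 12 rose and 0 fell, with a median of 0.26 (camera adjusted p = 9.52e-17); adjusted over the list alone, 19 rose and 5 fell. In the list of ATF4 and CHOP pathway genes, which respond to phosphorylation of the translation factor eIF2 alpha, 3 of 27 rose: ATF3, CHAC1 (0.62 ± 0.12) and ATF4 itself (0.47 ± 0.07). Adjusted over the list alone, 5 rose and 2 fell. This list had a camera adjusted p of 0.0419 and an adjusted p of 0.0747 with an estimated correlation. Its call was also lost without untreated replicate 1, 1 h replicates 1 and 4 or 6 h replicate 3 (adjusted p up to 0.168). The 18 cholesterol synthesis genes had a median of 0.13 (camera adjusted p = 0.00150), although 0 were called over all genes and 2 rose adjusted over the list alone. INSIG1, a regulator of sterol sensing, had the largest statistic among them, at 0.38 ± 0.10 (limma adjusted p = 0.137).

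The other 3 shifted lists moved down. Of 13 NF-kappaB targets, 3 fell and 0 rose (median -0.19, camera adjusted p = 8.18e-06; the same adjusted over the list alone): NFKBIA, CXCL8 and NFKB1 (-0.44 ± 0.09). The 23 ribosome biogenesis genes had a median of -0.10 (camera adjusted p = 5.60e-04). Of these, 0 were called over all genes and 5 fell adjusted over the list alone; POLR1B, a subunit of RNA polymerase I, stood at -0.30 ± 0.07 (limma adjusted p = 0.101). Of 367 genes with a ZNF symbol, most of which encode DNA-binding zinc finger proteins, 3 fell (median -0.05, camera adjusted p = 0.00324; 15 fell adjusted over the list alone). They were ZNF668 (-0.56 ± 0.08), ZNF232 (-0.55 ± 0.08) and ZNF573 (-0.43 ± 0.06). With an estimated correlation, 5 of the 6 shifted lists kept their call.

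DNAJB1, BAG3, DDIT3 and HMOX1, which rose at 6 h, had not passed the test at 1 h. DNAJB1 stood at -0.31 ± 0.08 (limma adjusted p = 0.132), BAG3 at -0.10 ± 0.08, DDIT3 at 0.13 ± 0.15, HMOX1 at 0.07 ± 0.10 and PSMB5, a catalytic subunit of the proteasome, at -0.14 ± 0.07. Of 24 hypoxia targets, 3 fell (ANKRD37 by 0.50, SLC2A3 by 0.44 and NDRG1 by 0.40 on the log2 scale; 5 fell and 1 rose adjusted over the list alone), without a shift of the list (camera adjusted p = 0.0887). The remaining 18 tested lists were not shifted; Wnt targets had a median of 0.02 and a mean of -0.03. The ITSN1 probe set 209297_at stood at -0.84 ± 0.15 and the tachykinin gene TAC1 at -0.67 ± 0.13. The other ITSN1 probe sets had changes between 0.10 and 0.43, and the mean of all of them was -0.05 with the call lost.

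Calls near the threshold at 1 h depended on single arrays. NFKB1 was lost without any 1 of the 12 arrays (adjusted p up to 0.128), and TAC1 without any but 6 h replicates 2 and 4 (up to 0.119). SLC2A3 was lost without any but 1 h replicate 4 and 6 h replicates 2 and 4 (up to 0.119), and NDRG1 without any but 1 h replicate 2 and 6 h replicates 2 and 4 (up to 0.107). CHAC1 was lost without any but untreated replicate 3 and 6 h replicates 1, 2 and 4 (up to 0.108), and ITSN1 without untreated replicates 1 to 3 or 1 h replicates 2 and 4 (up to 0.0898).

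**Figure D1:**
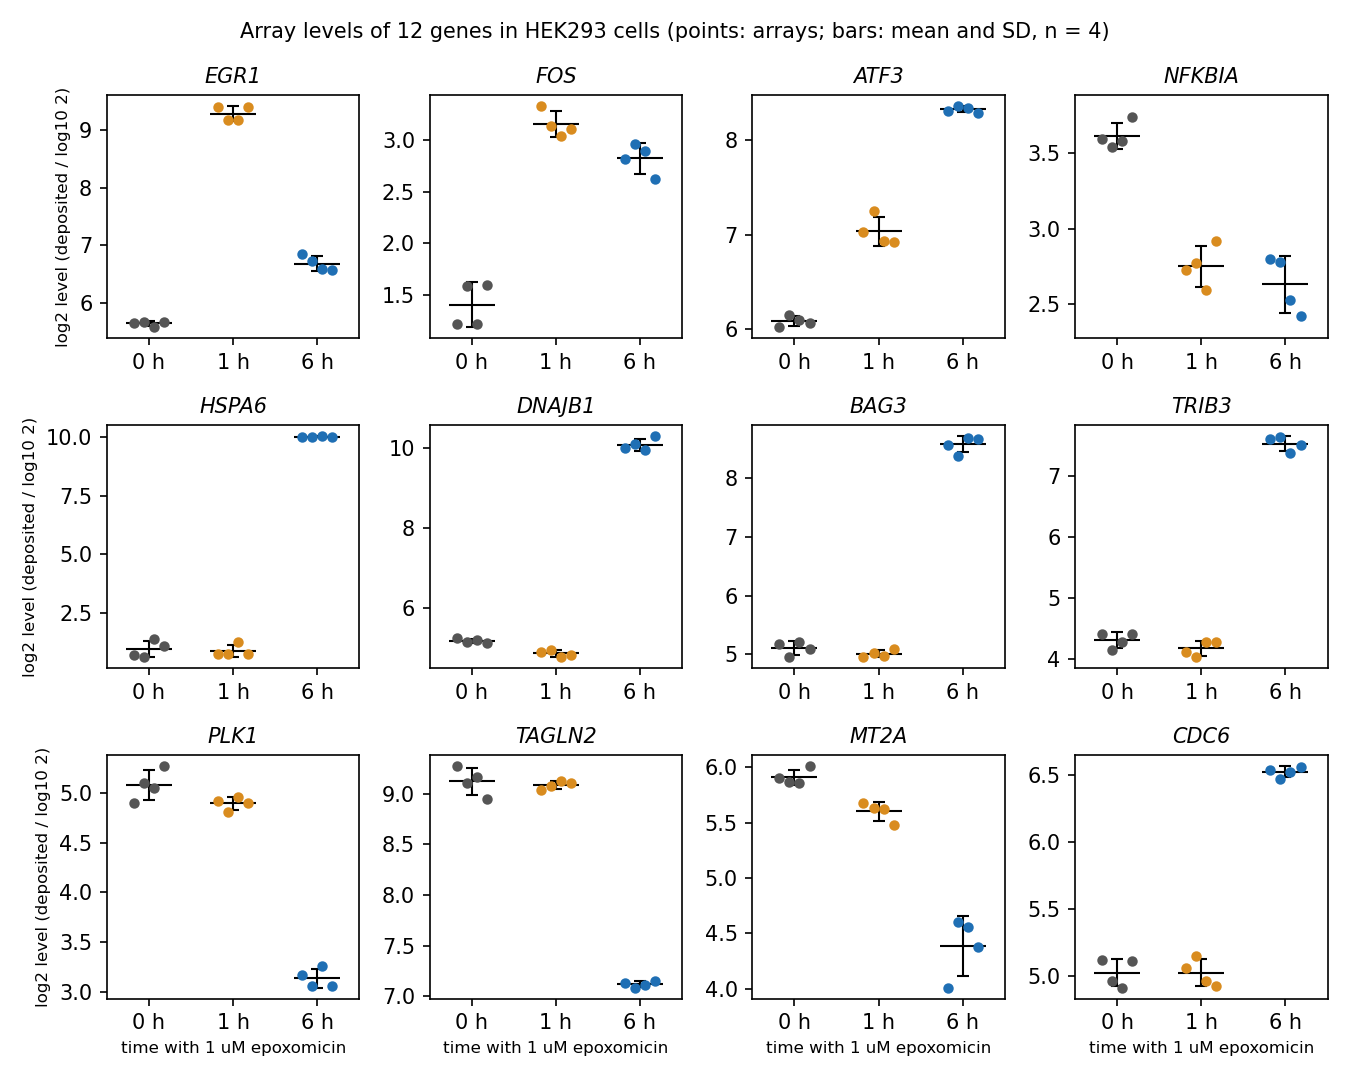
Log2 level of 12 genes on each array (points) with the mean and SD of each group (bars, n = 4) against time with epoxomicin; each panel has its own vertical axis. EGR1 stood highest at 1 h (log2 9.29 against 5.65 at 0 h), whereas HSPA6, DNAJB1, BAG3 and TRIB3 stood at 6 h above all arrays of the other groups.

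After 6 h, heat shock and integrated stress response genes rose most, and genes of mitosis, respiration, histones and metallothioneins fell. HSPA6 (probe set 213418_at), an inducible member of the HSP70 chaperone family, rose by log2 9.05 ± 0.15 (532-fold; limma adjusted p = 9.02e-14); its level was below the array median on 3 of 4 arrays at 0 h, so the size of the change is uncertain, and another probe set gave 8.41. DNAJB1, an HSP40 co-chaperone, rose by 4.91 ± 0.08 (30.1-fold), ZFAND2A, a proteasome-associated zinc finger protein gene, by 4.18 ± 0.10, BAG3 by 3.47 ± 0.08, the pseudokinase gene TRIB3 by 3.22 ± 0.09 and HSPH1 by 2.94 ± 0.06. The falls were led by MYL6, a myosin light chain (-2.46 ± 0.08), DMAC1, an assembly factor of respiratory complex I (-2.32 ± 0.08), the Notch target HES1 (-2.28 ± 0.12), PNRC1 (-2.04 ± 0.16), TAGLN2, an actin-binding protein (-1.999 ± 0.07), and the mitotic kinase PLK1 (-1.93 ± 0.08). Other probe sets of MYL6 and DMAC1 gave -0.10 and -0.90, and those of TAGLN2 and HES1 gave -1.73 and -1.55.

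At 6 h, 6630 of 12928 genes passed (3042 rose, 3588 fell), of which 480 changed at least 2-fold (213 rose, 267 fell). The median over all genes was -0.02. No untreated array was taken at 6 h, so a change over time in culture is part of every value. Control probe sets moved as well: the signal of Alu repeats was 0.68 higher than at 0 h, and the 3' and 5' ACTB controls stood at -0.52 and -0.68 (exact permutation p = 0.0286 each, the smallest possible), while 3' GAPDH stood at -0.02. The Alu probe set is among the brightest, where quantile normalization sets values by rank, so the size of its difference is uncertain.

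Of 27 heat shock proteins and co-chaperones, most of them cytosolic but with the mitochondrial HSPD1 and HSPE1 among them, 25 rose and 0 fell, with a median of 0.86 (camera adjusted p = 2.37e-13), and the counts were the same adjusted over the list alone. In the list of ATF4 and CHOP pathway genes, 25 of 27 rose and 1 fell, also adjusted over the list alone (median 1.25, camera adjusted p = 5.39e-16). TRIB3, SESN2 (2.71 ± 0.12) and ATF3 (2.24 ± 0.08) led this list, and DDIT3, which encodes CHOP, rose by 1.08 ± 0.15; the member that fell was ATF5 (-0.33), named after its value was seen. Of 17 aminoacyl-tRNA synthetase genes, which load amino acids onto tRNAs, 7 rose and 1 fell, also adjusted over the list alone. NARS1 rose by 1.17 ± 0.06, CARS1 by 1.09 ± 0.07 and YARS1 by 0.95 ± 0.10; the list's camera adjusted p was 0.00323, and the adjusted p was 0.129 with an estimated correlation.

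Proteasome genes went in different directions by subunit. Of 28 subunit genes, 14 rose and 5 fell, also adjusted over the list alone (median 0.17, camera adjusted p = 0.0444; adjusted p = 0.298 with an estimated correlation). The regulatory particle genes PSMD12, ADRM1 and PSMC4 rose by 1.40 ± 0.07, 0.90 ± 0.07 and 0.83 ± 0.08. PSMB5, a catalytic subunit, fell by 0.51 ± 0.07 on the log2 scale, and so did the core particle genes PSMA2 (-0.62), PSMB6 (-0.46), PSMA3 (-0.24) and PSMA4 (-0.24), named after their values were seen. The list's call was lost without untreated replicate 4, 1 h replicate 3 or 6 h replicates 1 and 2 (adjusted p up to 0.0748). Among 28 genes of ubiquitin, p97 and proteasome assembly, 12 rose and 4 fell (6 adjusted over the list alone) and the list was not shifted (median 0.12, camera adjusted p = 0.0768). The assembly chaperone genes PSMG4 and PSMD10 changed by -1.64 ± 0.09 and -1.51 ± 0.07, with another PSMG4 probe set at 0.23. The polyubiquitin gene UBB rose by 1.08 ± 0.07.

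Of 25 endoplasmic reticulum chaperone and unfolded protein response genes, 10 rose and 3 fell, also adjusted over the list alone. XBP1, a transcription factor of this response, rose by 1.27 ± 0.10, its activating kinase gene ERN1 by 0.82 ± 0.06, HERPUD1 by 0.75 ± 0.09 and the chaperone gene HSPA5 by 0.65 ± 0.07. The list had a median of 0.17 and a camera adjusted p of 0.0385, with an adjusted p of 0.0628 with an estimated correlation and of 0.0564 without untreated replicate 1. Of 22 oxidative stress and NRF2 pathway genes, 12 rose (13 adjusted over the list alone) and 3 fell (median 0.21, camera adjusted p = 0.00187). MAFF rose by 2.24 ± 0.06, GCLM, a subunit of the enzyme that starts glutathione synthesis, by 1.47 ± 0.09, SRXN1 by 1.42 ± 0.10 and the haem oxygenase gene HMOX1 by 1.16 ± 0.10. Of 36 immediate early genes, 22 rose and 3 fell, also adjusted over the list alone (median 0.39, camera adjusted p = 1.21e-06). GADD45B rose by 2.33 ± 0.10, ARC by 2.27 ± 0.14, ZFP36 by 1.86 ± 0.12, FOS by 1.42 ± 0.11 and MYC by 0.61 ± 0.10; JUN stood at 0.07 ± 0.08 and was called (0.27) when its probe sets were averaged. ARC was below the array median on 3 of 4 arrays at 0 h.

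Of 30 mitosis and G2/M genes, 25 fell and 0 rose (27 fell adjusted over the list alone), with a median of -0.72 (camera adjusted p = 1.10e-11). Besides PLK1, the securin gene PTTG1 (-1.51 ± 0.06) and the ubiquitin-conjugating enzyme gene UBE2C (-1.39 ± 0.08) fell most. Of 21 replication-dependent histone genes, 13 fell and 0 rose, also adjusted over the list alone (median -0.51, camera adjusted p = 0.00187), among them H1-2 (-1.61 ± 0.10) and H2AC6 (-1.11 ± 0.09). Of 31 DNA replication genes, 15 rose and 7 fell, also adjusted over the list alone. CDC6, which loads the replicative helicase, rose 2.82-fold and CCNE1 by log2 0.75 ± 0.07. This list had a median of 0.19 and a camera adjusted p of 0.0455, with an adjusted p of 0.149 with an estimated correlation. Its call was lost without untreated replicate 4, 1 h replicates 2 and 3 or 6 h replicate 1 (adjusted p up to 0.0624).

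Of 30 oxidative phosphorylation genes, 21 fell and 0 rose (median -0.41, camera adjusted p = 4.55e-07; 21 fell and 1 rose adjusted over the list alone). ATP5MC1, a subunit of ATP synthase, changed by -1.74 ± 0.07, COX7B of cytochrome c oxidase by -1.60 ± 0.06 and SDHC of succinate dehydrogenase by -1.50 ± 0.07. Other probe sets gave smaller falls: -0.34 for COX7B and between -1.40 and -0.25 for SDHC. The 6 metallothionein genes, whose products bind zinc and copper, all fell, also adjusted over the list alone (median -0.94, camera adjusted p = 5.79e-04). MT2A changed by -1.52 ± 0.11 and MT1X by -1.24 ± 0.09; their sequences are close enough that the signals cannot be fully separated. Of 23 ribosome biogenesis genes, 12 rose and 1 fell, also adjusted over the list alone (median 0.28, camera adjusted p = 0.00142), with NOP58 at 1.02 ± 0.17, UTP4 at 0.87 ± 0.07 and BYSL at 0.80 ± 0.09. Of 367 genes with a ZNF symbol, 153 rose and 35 fell, also adjusted over the list alone (median 0.16, camera adjusted p = 2.14e-05), with ZNF408 at 1.56 ± 0.15 and ZNF580 at -1.34 ± 0.15. Of the 14 lists shifted at 6 h (10 up, 4 down), 10 kept their call with an estimated correlation. The calls of endoplasmic reticulum, proteasome and DNA replication genes were also lost when the list test used ranks and when the filter stood at the 75th percentile.

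The other tested lists were not shifted at 6 h, though members changed. Of 26 autophagy genes, 12 rose and 6 fell (7 adjusted over the list alone; camera adjusted p = 0.112): MAP1LC3B rose by 1.13 ± 0.06, GABARAPL1 by 0.91 ± 0.07 and the cargo receptor gene SQSTM1 by 0.78 ± 0.06. Of 19 p53 targets, 3 rose and 9 fell (camera adjusted p = 0.299). GADD45A rose by 2.07 ± 0.10, DDB2 changed by -1.16 ± 0.10, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, stood at 0.10 ± 0.07 (limma adjusted p = 0.255). Of 13 NF-kappaB targets, 1 rose and 5 fell, with a median of 0.00 and a mean of -0.14 (camera adjusted p = 0.603); NFKBIA stood at -0.97 ± 0.10 and CCL2 at -0.73 ± 0.10. Of 16 BCL2 family genes, which set the threshold of apoptosis, 5 rose and 5 fell (camera adjusted p = 0.944): BIK stood at 0.89 ± 0.12, MCL1 at 0.50 ± 0.08 and BAX at -0.67 ± 0.09. Of 24 hypoxia targets, 8 rose and 6 fell, with a median of -0.08 and a mean of 0.04 (camera adjusted p = 0.798), VEGFA at 1.09 ± 0.09 and LDHA at -1.09 ± 0.07. Of 13 Wnt targets, 4 fell and 0 rose, with a median of 0.00 and a mean of -0.18 (camera adjusted p = 0.544), led by CCND1 at -1.20 ± 0.13. Except for the autophagy count given, all these counts were the same adjusted over the list alone.

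Of 18 cholesterol synthesis genes, 6 rose and 6 fell (camera adjusted p = 0.757), and of 31 cytosolic ribosomal protein genes, 4 rose (3 adjusted over the list alone) and 4 fell (camera adjusted p = 0.693). Of 17 interferon response genes, 2 rose and 4 fell (3 adjusted over the list alone; camera adjusted p = 0.798). Of 8 keratin epithelial markers, 3 rose and 1 fell (median 0.15, camera adjusted p = 0.278). Only 4 fibroblast, 4 blood cell and 1 hepatocyte markers were tested, too few for the list test, with medians of -0.21, 0.11 and 0.07. Of these, 2 fibroblast markers fell, among them LUM (-0.62 ± 0.12), and 1 blood cell marker rose (0 adjusted over the list alone).

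**Figure D2:**
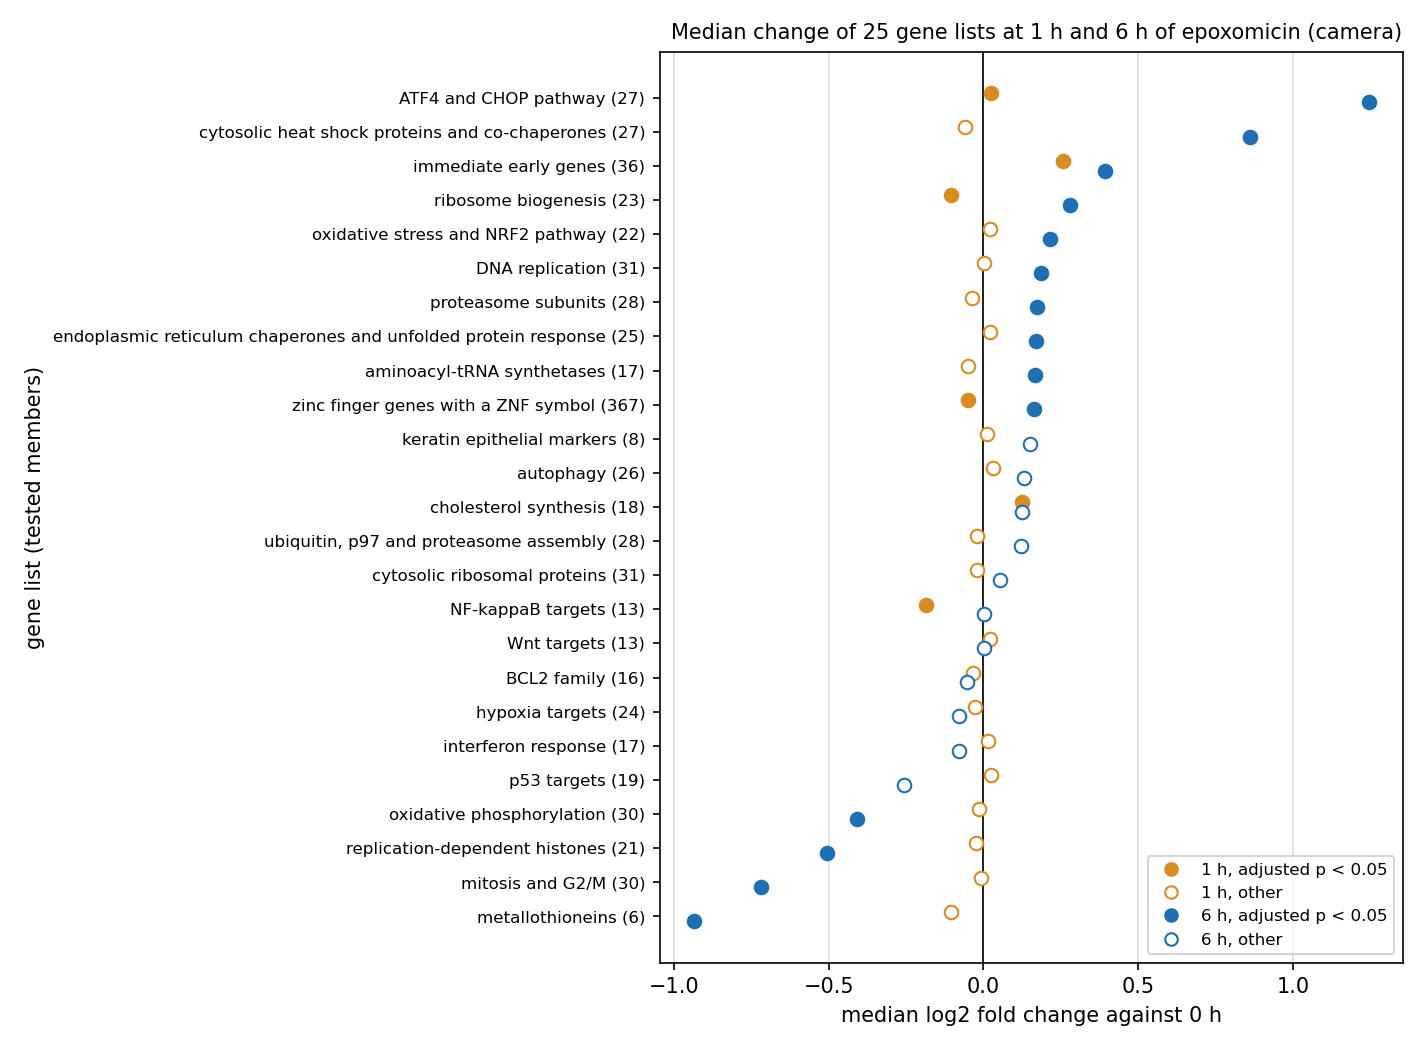
Median log2 fold change against 0 h of the tested members of 25 gene lists at 1 h (orange) and 6 h (blue), with filled circles for lists whose camera adjusted p was below 0.05. The list of ATF4 and CHOP pathway genes stood highest at 6 h (1.25) and the metallothioneins lowest (-0.94), and ribosome biogenesis genes stood below 0 at 1 h (-0.10) and above 0 at 6 h (0.28).

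Between 1 h and 6 h, the lists of heat shock proteins and of ATF4 and CHOP pathway genes were shifted up. Immediate early genes went both ways. DNAJB1 and ZFAND2A stood 5.22 ± 0.08 and 4.36 ± 0.10 higher at 6 h than at 1 h. HSPA6 was below the array median on all 4 arrays at 1 h, so the size of its rise (9.12, and 8.34 for another probe set) is uncertain. EGR1 fell by 2.60 ± 0.08 on the log2 scale from its 1 h level and was 1.04 ± 0.08 above 0 h, where its other probe sets gave 0.27 (not called) and 0.54. EGR3 stood at 0.13 ± 0.17 against 0 h (limma adjusted p = 0.559). ATF3 rose by a further 1.29 ± 0.08. MYL6 (-2.40 ± 0.08) and DMAC1 (-2.23 ± 0.08) changed as against 0 h. Of 12928 genes, 6693 differed between the times (3111 higher and 3582 lower at 6 h), 508 of them at least 2-fold (233 higher, 275 lower).

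Of the 25 lists, 12 were shifted between 1 h and 6 h, 8 up and 4 down, and 7 kept their call with an estimated correlation. Among ATF4 and CHOP pathway genes 24 of 27 rose, with a median of 1.28 and STC2, a secreted glycoprotein gene, at 2.06 ± 0.09. Ribosome biogenesis genes had a median of 0.35 (14 rose, 0 fell), led by NOP58 at 1.31 ± 0.17, and genes with a ZNF symbol one of 0.22 (164 rose, 26 fell). Immediate early genes, with 16 higher and 9 lower (18 and 9 adjusted over the list alone), were not shifted (median 0.21, camera adjusted p = 0.0647). The calls of proteasome subunits (adjusted p = 0.273 with an estimated correlation), endoplasmic reticulum genes (adjusted p = 0.0609), aminoacyl-tRNA synthetases (adjusted p = 0.0977), NRF2 pathway genes (adjusted p = 0.0585) and histones (adjusted p = 0.0585) were lost when the correlation was estimated.

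The changes at 1 h and 6 h, both taken against the same 4 untreated arrays, correlated weakly across genes. Pearson's r was 0.1004 and Spearman's rho 0.0948 over 12928 genes, which are not independent replicates. Unchanged groups simulated against the same controls gave r = 0.498 (0.471 to 0.524 in 100 simulations), and splitting the controls so that each comparison had its own gave a mean r of 0.00418 over 6 assignments. The covariance was 0.00727 against a simulated 0.00700 (0.00638 to 0.00749), and its mean was 0.00034 with split controls. Over all genes, the covariance was thus no larger than the shared controls alone can give. Of the 57 genes called at 1 h, 44 were also called at 6 h. EGR1, FOS and IER2 were among 20 that rose at both times, where independent lists would share 6.12, and 11 fell at both times against 8.60. Another 11 fell at 1 h and rose at 6 h, against 7.29, and 2 rose and then fell, against 7.22. Independent lists leave out the shared controls and the simulated value leaves out the effects. With the controls split so that each comparison had its own, 13 to 22 genes were called at 1 h. Of these, 10 to 13 were called in the same direction at 6 h, against 2.79 to 4.76 for independent lists, and 1 to 6 in the opposite direction.

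**Figure D3:**
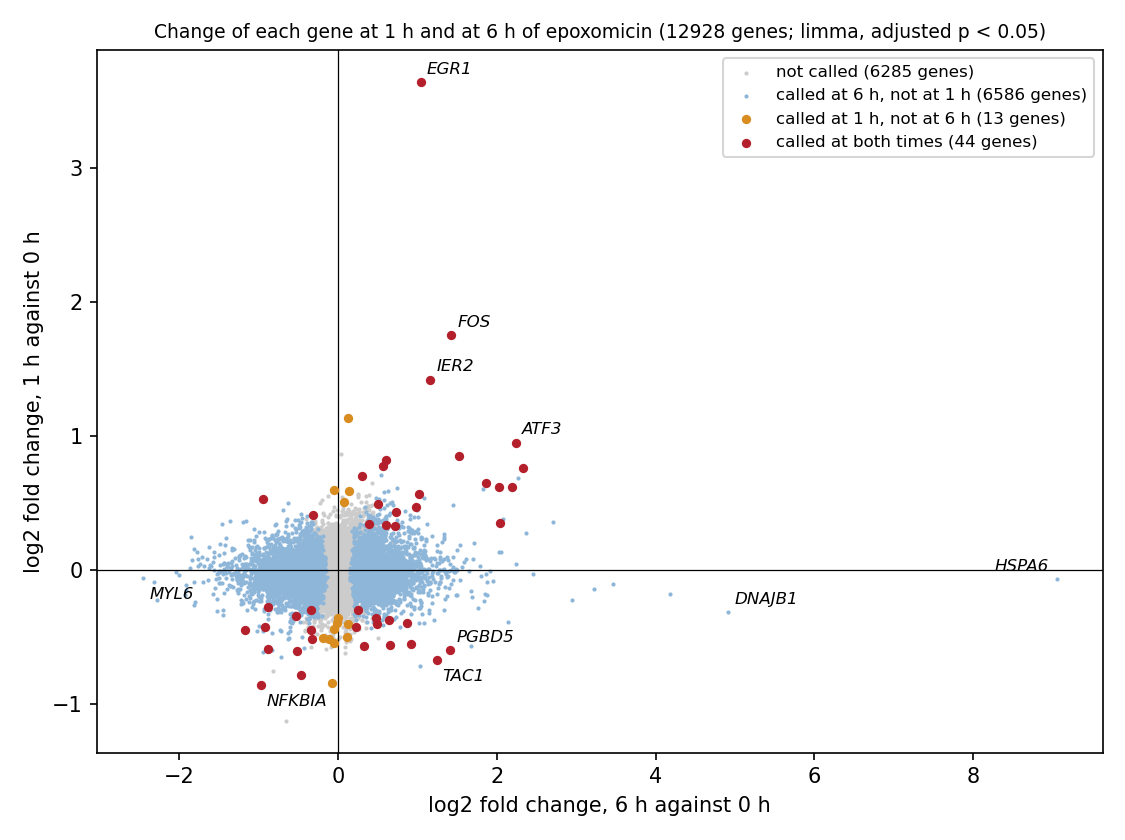
Log2 fold change of each of 12928 genes at 1 h (vertical axis) against that at 6 h (horizontal axis), coloured by limma calls at an adjusted p below 0.05. Of the 57 genes called at 1 h, 44 were called at both times (red), and HSPA6 lay at 9.05 on the horizontal axis with -0.07 on the vertical axis.

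The 3'/5' ratio of control transcripts did not separate the groups. For GAPDH the log2 ratio was 0.42 ± 0.20, 0.47 ± 0.11 and 0.52 ± 0.10 (SD, n = 4) at 0 h, 1 h and 6 h, and the difference between 6 h and 0 h had an exact two-sided permutation p of 0.429. For ACTB it was 0.63 ± 0.21, 0.56 ± 0.13 and 0.79 ± 0.10, with an exact p of 0.229. Over the 12 ratios and comparisons tested, the lowest exact p was 0.0571, for ACTB between 6 h and 1 h, and its adjusted p was 0.617.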

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

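The list of small nucleolar RNA hosts was assembled after SNHG17 and EPB41L4A-AS1 had been seen among the largest rises, and the tests of long non-coding RNA in general and of that list without some members were chosen after the results they bear on.

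Across 99 named genes in 3 groups of 4 arrays, 297 sets of values, 12 sets (4.04%) held an array set far apart from the other 3, where chance alone gives about 1 in 20. In the 6 h group these were COX7B on replicate 4 (log2 level 6.66), DDB2 on replicate 3 (1.83), HES1 on replicate 1 (1.95), IRF1 on replicate 1 (2.53) and POLR1B on replicate 2 (4.97). In the 1 h group they were HSPA6 on replicate 3 (1.26), MT1H on replicate 2 (3.19), PSMC4 on replicate 3 (6.54) and TAC1 on replicate 2 (5.06), and at 0 h POLR1B on replicate 2 (4.76), VEGFA on replicate 4 (4.10) and ZNF232 on replicate 4 (3.84). No array had more than 2 of them.

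The responses at 1 h and 6 h differed by the direct test between the times for 6693 of 12928 genes, and for 94 of the 99 named genes. Most named genes were chosen for large changes in these data, so their higher share follows in part from the choice. 13 genes were called in opposite directions at the times, 11 of them lower at 1 h and higher at 6 h. The log2 difference between 6 h and 1 h was 2.01 for PGBD5, 1.91 for TAC1, 1.47 for ZNF232 and 0.89 for both NDRG1 and ZNF668. The splicing factor gene SRSF5 went from 0.53 at 1 h to -0.94 at 6 h and SYTL5, like it chosen after its values were seen, from 0.41 to -0.32. As lists, ribosome biogenesis genes and genes with a ZNF symbol also turned from below to above 0 h, with median differences of 0.35 and 0.22.

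Probe sets that name no single gene carried signals outside the comparisons of named genes. At 6 h, 587 of 1143 kept probe sets with several symbols and 931 of 3257 not listed changed (limma). Of those with several symbols, 200800_s_at rose by log2 6.15 ± 0.16 (71.0-fold) and 200799_at by 4.34 ± 0.15, whereas 216384_x_at stood at -1.95 ± 0.20 and 203880_at at -1.55 ± 0.10. Of those not listed, 242300_at stood at 2.28 ± 0.08, 218559_s_at at 1.70 ± 0.08, 207243_s_at at -2.38 ± 0.08 and 229817_at at -1.42 ± 0.10. Probe set 218559_s_at was already higher at 1 h (0.73, adjusted p = 0.00102). The Alu control probe set, which detects a repeat found in many transcripts, was 0.68 higher at 6 h than at 0 h (exact permutation p = 0.0286, the smallest possible). Its mean log2 level was 13.4 at 0 h and 1 h and 14.1 at 6 h, among the brightest probe sets. On quantile-normalized arrays such a value is set by rank, so the size of the difference is uncertain.

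Of 24 probe sets of non-coding genes that host small nucleolar RNAs in their introns, 15 rose at 6 h and 3 fell, 11 of them rising at least 2-fold, with a median of 0.55 against 0.05 at 1 h; among genes with 1 symbol, chosen after their values were seen, SNHG17 rose by 2.46 ± 0.07, EPB41L4A-AS1 by 2.06 ± 0.07 and ZFAS1 by 1.70 ± 0.07. A rise of every transcript that carries such an RNA, or hybridisation of the small RNAs themselves, would raise coding hosts alike; 38 probe sets of coding hosts had a median of 0.16, a difference of -0.38 (permutation p = 0.0173, 100000 resamples, two-sided). Without SNHG17, EPB41L4A-AS1 and ZFAS1 12 of 21 rose, with a median of 0.43, but the difference from coding hosts was -0.27 (permutation p = 0.136), so this explanation cannot be told apart. A general rise of long non-coding RNA is argued against by a median of -0.14 over 677 others. Signal level is argued against by 10000 random lists matched on 0 h level, of which 0% reached the median, with and without those 3 genes. Without the probe sets at least 2-fold up, 4 of 13 rose and 3 fell, with a median of -0.08. Then 61.6% of matched lists reached the median, and the difference from coding hosts was 0.24 (permutation p = 0.163). That removal picks probe sets by their change and so lowers the median by itself, and no conclusion is drawn from it. What also stays open is a change in synthesis or turnover of these host RNAs, which was not tested, and the time in culture, which the design does not separate from treatment.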

How the results depend on the processing

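The alternative that keeps genes above the array median on every 0 h array was added after the data were seen. The number of genes changed at 1 h (57) depended on the processing: 25 with no filter, 128 with a filter at the 75th percentile, 36 with the most variable probe set, 142 with an intensity trend and robust prior, 22 at an adjusted p of 0.01, 32 with only the 8 arrays compared and 87 with genes above the median on every 0 h array. A filter changes how many genes share the adjustment and fewer arrays leave fewer degrees of freedom; the cause of the other differences was not tested. The replicate number as a block gave 24, 6454 and 6487 genes at 1 h, at 6 h and between the times. The numbers share no source in the labels: correlations of same-numbered arrays' deviations ran from -0.145 to 0.0425, 0 of 12 above 0.1, and in 2 of 12 pairs the own number correlated best.

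Lists shifted between 1 h and 6 h (12) were 7 with an estimated correlation and 22 with fry, which asks another question. The correlation of changes at 1 h and 6 h (0.1004) was 0.165 with no filter, 0.0562 with the 75th percentile, 0.00418 with split controls and 0.0665 with genes above the median on every 0 h array. The ACTB ratio against the middle instead of the 5' probe set reversed at 1 h (0.149 against -0.0703) and between the times (-0.0522 against 0.234); the cause was not tested.

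Leaving out single arrays gave 28 to 66 genes at 1 h (lowest without untreated replicate 2 and without 1 h replicate 2), 6179 to 6580 at 6 h and 6259 to 6687 between the times. For 2-fold changes it gave 3 to 4, 457 to 499 and 500 to 528, for lists 5 to 7, 12 to 14 and 12 to 13, and for the correlation 0.0865 to 0.129. The GAPDH ratio at 1 h ranged from -0.00610 to 0.115, with the sign turned without untreated replicates 1 (-0.00581) and 4, and HMOX1 at 1 h ranged from -0.0135 (without 1 h replicate 4) to 0.12002. Of 1428 such runs of named genes 53 lost the call, and of 384 runs of lists 13 did. The 53 were all at 1 h: NFKB1 (12), TAC1 (10), SLC2A3 (9), NDRG1 (9), CHAC1 (8) and ITSN1 (5). The 1428 runs include those at 6 h and those of genes that had no call to lose, so they do not give the rate of loss at 1 h.

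Under the other alternatives, named genes stayed on their side of the threshold in 1371 comparisons, lost the call in 38 and gained it in 7; lists stayed in 446 and lost it in 34. None of these changed direction. The counts take in quantile normalization and median centring, and named genes that had no call to lose, so they overstate stability. Quantile normalization moved nothing and median centring only 6693 to 6691 genes between the times, because the table was already quantile-normalized, so both say nothing on stability. Both planned pseudocounts were not run, since the table holds log values. Low signal limits what can be seen. On the log2 scale, the median SD within groups was 0.24 for probe sets with a mean deposited value between 0.2 and 0.4. For those between 1.5 and 2 it was 0.10.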

Other observations

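The gene lists of this part were assembled after the largest falls at 6 h had been seen, members named from them were chosen after their values were seen, and the tests of RNA degradation and of other splits were chosen after the results they bear on.

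Genes of the actin cytoskeleton fell at 6 h. Of 30 tested members, 24 fell and 0 rose, 9 of them at least 2-fold, with a median of -0.42 (camera p adjusted over the 3 lists of this part, adjusted p = 1.16e-08, and adjusted p = 0.00169 with an estimated correlation). Lists matched on 0 h level were not drawn for these genes, so a fall of bright genes in general was not tested. The list's p-values are not independent of these data, since it was prompted by MYL6 and TAGLN2. Without them 22 of 28 fell (median -0.39, adjusted p = 2.91e-07, and adjusted p = 0.00328 with an estimated correlation), and without all members at least 2-fold down 15 of 21 did (median -0.27, adjusted p = 0.00125, and adjusted p = 0.0178 with an estimated correlation). Besides these, TAGLN stood at -1.81 ± 0.11, the thymosin genes TMSB10 and TMSB4X at -1.55 ± 0.08 and -1.31 ± 0.10, the tropomyosin gene TPM1 at -1.48 ± 0.08 and ACTB at -1.23 ± 0.09, with another ACTB probe set at -0.68 and the ACTB controls at -0.52 and -0.68. At 1 h the list was also shifted down (median -0.07, camera adjusted p = 0.0198), a call lost with an estimated correlation (adjusted p = 0.1202), and 1 member, VCL, passed the test (-0.30 ± 0.06). ACTB is often taken as a reference transcript, and its level moved here, on these quantile-normalized arrays, by more than the spread between replicates.

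Genes of mitochondrial ribosomes and of mitochondrial import and folding went both ways at 6 h. Of 72 mitochondrial ribosomal protein genes, 37 fell and 12 rose, with MRPL51 at -1.22 ± 0.06 and MRPS33 at -1.11 ± 0.07. Of 27 genes of mitochondrial import and protein folding, 10 rose and 5 fell (median 0.11, camera adjusted p = 0.172). The matrix chaperone genes HSPD1, GRPEL1, HSPA9 and HSPE1 rose by 0.86 ± 0.10, 0.71 ± 0.08, 0.69 ± 0.07 and 0.61 ± 0.07, and the other genes that rose included YME1L1 (0.59), TIMM44 (0.59) and TOMM20 (0.41). TIMM8B stood at -1.36 ± 0.11, but another of its probe sets gave -0.15.

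The fall of oxidative phosphorylation genes (median -0.41) was set against signal level and genomic gene length. Lists matched on 0 h level had a median of medians of -0.13, and 0.79% of 10000 of them had a median as low. Of lists matched on genomic gene length 0% did, and transcript length was not tested. RNA degradation cannot be told apart from the other explanations: the ACTB 3'/5' log2 ratio was 0.16 higher at 6 h than at 0 h, with a 95% interval of -0.08 to 0.41, and that of GAPDH ran from -0.13 to 0.33. The median of mitochondrial ribosomal protein genes, -0.24 (camera adjusted p = 0.00232, but adjusted p = 0.224 with an estimated correlation), is consistent with a fall of nuclear-encoded mitochondrial genes in part only, since the list of import and folding genes had a median of 0.11 and 10 of its members rose. HSPD1, GRPEL1, HSPA9 and HSPE1 were among those 10, and HSPD1 and HSPE1 also belong to the list of heat shock proteins. The import and folding list was not tested without them. An effect of treatment stays open beside time in culture.

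Probe sets of the same gene often changed by different amounts at 6 h. Over 240 genes whose brightest probe set changed at least 2-fold, the next brightest showed 73.2% of that change at the median, and 8 had the opposite sign. Noise between replicates is argued against as the whole cause by the 57.9% of pairs that differed beyond the 95% limits of their standard errors. The share rose with the level of the dimmer probe set (Spearman rho = 0.606 across genes, permutation p = 1e-05, the smallest that 100000 resamples give), from 47.6% in the dimmest group of 80 to 91.9% in the brightest. Compression of low signals on the deposited scale may therefore account for part of it; transcript variants seen by only 1 of the probe sets were not tested. Of 4395 genes with several kept probe sets and at least 1 of them called at 6 h, 123 had probe sets called in both directions (limma); at 1 h only 31 such genes had a call, too few to compare.

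Each comparison of 4 against 4 arrays allows 35 splits. For genes changed, 1 of 35 splits, the real one, reached 57 at 1 h (highest other 1), 6630 at 6 h (highest other 0) and 6693 between the times (highest other 1). For 2-fold changes 1 of 35 reached 4, 480 and 508 (highest other 0 in each). For lists shifted at 1 h 1 of 35 reached 6 (highest other 3). For these 7 counts the real split stood alone, at 1 of 35, the smallest share that this test can give. Splits that mix the groups add the group difference to the spread, so their low gene counts do not show how many calls chance gives. Time in culture or handling could separate the real groups in the same way. For lists shifted at 6 h, 3 of 35 splits reached 14 (highest other 14), and between the times 3 of 35 reached 12 (highest other 12), so this test does not exclude chance for these counts. The other splits that matched them kept 3 of 4 arrays of each group together, which leaves part of the group difference in place, and called 0 genes. The 18 splits that divided both groups evenly, examined last, shifted 0 lists at 6 h and at most 1 between the times.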
